A study of Caenorhabditis elegans with 12 samples.

How the data were processed

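RNA was measured in 12 samples of Caenorhabditis elegans, 3 of WT (N2) and 3 each of the strains labelled crh-1 null, tax-6 null and aak-2 o/e. Per the labels' protocols, embryos from bleached adults hatched overnight without food, 750 first-stage larvae were placed on each plate with OP50 bacteria, and 3000 worms per sample were frozen at the L4 stage, at times chosen to allow for strain differences in the speed of development. The labels state both that larvae were plated together and that replicate pools of a strain came from separate days. RNA of all samples was extracted together 12 hours before the arrays were run, and it was labelled with the Affymetrix 3' IVT kit, per the labels' protocols. Harvest times, which replicate was prepared on which day and scan dates are not given in the sources used here, so no batch could be tested except through the replicate number.

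The authors deposited 1 table of log2 values for 22625 probe sets on the 12 arrays. They were made with GCOS 1.4 and GCRMA, per the submitters' processing notes; the version and settings of GCRMA are not given in the sources used here. GCRMA subtracts background with the probes' base content, normalizes between arrays and summarises each probe set on the log2 scale. The values had a common floor: 29.8% of all values lay within 0.1 of the lowest value, 2.11, so changes of dim probe sets are compressed. Fold changes against a strain whose 3 arrays all lay below a log2 value of 4 are therefore given as lower bounds. Array medians lay between 5.32 and 5.45. No 2 arrays held identical values.

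Probe sets were named through the platform annotation supplied with the table, with symbols updated through gene IDs to the WBcel235 gene table. There were 20766 probe sets with 1 gene symbol, 887 with several, 895 with none listed and 77 control probe sets. Of the probe sets with 1 symbol, 20701 had a gene ID found in the gene table. No gene was named from a probe set with several symbols. No coordinates are given because the annotation names no genome build. Control probe sets were left out, and a probe set was tested when its log2 value was at least 4 on 3 or more arrays, which left 13396 probe sets. Of these, 12717 had 1 gene, for 10365 genes, each represented by its probe set with the highest mean over all arrays. Of 2057 genes with more than 1 probe set tested, 0 had probe sets called in opposite directions in crh-1 null, 8 in tax-6 null and 2 in aak-2 o/e. Probe sets with the suffix _s or _x can bind transcripts of related genes, so members of near-identical families such as collagens, yolk proteins and abu genes are uncertain as single genes.

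Each contrast was tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, default prior), with 1 mean per strain over all 12 arrays, tested both ways, and Benjamini-Hochberg adjustment over the probe sets tested at a threshold of 0.05. There were 8 residual and 3.63 prior degrees of freedom. The replicates were separate pools of animals. The comparisons were the 3 altered strains against WT and the 3 direct contrasts between them. Overlaps between comparisons that share the WT arrays were set beside independent lists. They were also set beside 100 simulations of unchanged groups, with all 12 arrays drawn around the WT means. Same-numbered replicates were checked for pairing through the correlations of their deviations from strain means.

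Gene lists were tested with camera at the preset correlation of 0.01, with Benjamini-Hochberg adjustment over all lists and the 3 comparisons with WT together and over the direct contrasts separately, and again with a correlation estimated per list. The 47 lists, the design, the alternatives and the rule for naming genes were fixed before the data were examined. The rule took, per strain against WT, genes past the threshold whose 3 values all lay outside the range of the 3 WT values: the 8 largest rises and 8 largest falls with a gene-class name and the 3 largest each way with a sequence name. It also took the 8 genes each way with the largest shared change in all 3 strains, 4 each way per pair of strains, 4 each way per direct contrast, the 4 members with the smallest adjusted p of a list that was called or had 3 or more members called, and crh-1, tax-6, aak-2, rol-6, unc-54, hsp-3, hsp-4, xbp-1, crtc-1, vit-2 and sod-3.

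The procedure was tested on simulated data drawn for the 13396 probe sets with 200 changed. A change of 2 on the log2 scale was recovered in 100%, 98.5% and 100% of probe sets in the comparisons of crh-1 null, tax-6 null and aak-2 o/e with WT, a change of 1 in 85.1%, 92.5% and 82.1%, and a change of 0.5 in 23.9%, 19.4% and 11.9%. False calls made up 5.44%, 4.11% and 5.15% of calls. On the real arrays 20.6%, 45% and 33.5% of genes were called, a far larger share than was changed here. The Benjamini-Hochberg adjustment is stricter when few probe sets change. These recovery rates therefore do not describe the real comparisons. A simulated shift of 0.5 in 32 genes, the proteasome subunits, was called by camera with either correlation. The simulated genes were drawn independently, while the correlation estimated for this list on the real arrays was 0.142. The simulation therefore does not show the power of camera with an estimated correlation on the real arrays.

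The alternatives were no filter or a stricter filter at a log2 value of 6, quantile normalization or median centring of the deposited values, the replicate number as a block, eBayes with trend and robust fitting, only the 2 strains compared, array weights, an adjusted p of 0.01, an additional 2-fold minimum, the mean of all probe sets of a gene, and each array left out in turn.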

Results

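Transcript levels were measured in 12 pools of whole Caenorhabditis elegans animals on Affymetrix arrays, 1 array per pool. The pools fell into 4 strains with 3 arrays each. WT was the laboratory strain N2, and the others were labelled crh-1 null (crh-1 encodes the transcription factor CREB), tax-6 null (tax-6 encodes the catalytic subunit of the calcium-dependent phosphatase calcineurin) and aak-2 o/e. The last strain carried a transgene with amino acids 1 to 321 of AAK-2, a catalytic subunit of the energy-sensing kinase AMPK, with the unc-54 3' untranslated region and rol-6 as marker. The series title placed AMPK, calcineurin, the CREB coactivator CRTC-1 and CREB in 1 longevity pathway, and each altered strain was compared with WT. Each pool held 3000 animals at the L4 larval stage, the last before adulthood. All values are deposited log2 values, given as mean ± SD over n = 3 arrays or as a log2 change ± SE from limma with 3 arrays against 3. Between 57.1% and 58% of the 22625 probe sets reached a log2 value of 4 on each array, and the number of arrays limited the precision. Arrays of a strain correlated across probe sets at r = 0.993 to 0.995 in WT, 0.993 to 0.994 in crh-1 null, 0.989 to 0.993 in aak-2 o/e and 0.974 to 0.994 in tax-6 null, where replicate 1 stood apart from the others. Probe sets are not independent replicates.

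The targeted genes were examined first, as a check of the labels. The detected probe set of crh-1 was higher in the arrays labelled crh-1 null, from 7.16 ± 0.09 to 8.62 ± 0.19, a log2 change of 1.46 ± 0.15 (adjusted p = 1.57e-05, higher in 3 of 3 arrays). A second crh-1 probe set lay at the lowest level, 2.12, on all 12 arrays. The only probe set of tax-6 reached a log2 value of 4 on 1 of the 12 arrays and was too dim for the filter, so it was tested apart from it, added to the 13396 probe sets. Its mean was 3.71 in WT and 3.24 in the arrays labelled tax-6 null (adjusted p = 0.0376), and no size is read from values this near the lowest level. That call ended with arrays centred on their medians, with the replicate block, with only the 2 strains compared (adjusted p = 0.0603, 0.0582 and 0.091) and without any single one of 6 arrays. These were WT replicate 1 (adjusted p = 0.159), tax-6 null replicates 2 and 3 (adjusted p = 0.0535 and 0.147) and each crh-1 null array (adjusted p = 0.0506 to 0.0514). In the arrays labelled aak-2 o/e, aak-2 was lower by 1 of its 2 probe sets (log2 change -0.47, adjusted p = 0.0129, and 0.0519 without aak-2 o/e replicate 2 or 0.0513 without WT replicate 2). The other did not pass (-0.41 ± 0.19, adjusted p = 0.126), but passed as lower with array weights (adjusted p = 0.0464) and without WT replicate 3 (log2 change -0.6, adjusted p = 0.034). One label field of these 3 samples reads aak-2 null while the title and strain fields describe overexpression. The marker rol-6 stood at 13.22 in WT and 12.93 in aak-2 o/e, and unc-54 lay barely past the threshold there (log2 change -0.32, adjusted p = 0.0496), a call lost with quantile normalization, median centring or the replicate block (adjusted p = 0.0619, 0.0509 and 0.0722) and without any single one of 11 arrays (adjusted p up to 0.151). Where the probes lie relative to the deletions, the transgene fragment and its 3' untranslated region is not given in the sources used here, so these levels check the labels only in part. Directions below are therefore those of the arrays labelled crh-1 null, tax-6 null and aak-2 o/e. No probe set measured crtc-1 alone.

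In the arrays labelled crh-1 null, the steepest falls in the deposited values were those of ttr-14, dos-2 and the collagen gene col-60. The largest rise was that of F26A1.8. The order of the falls is uncertain, since ttr-14 and dos-2 lay below a log2 value of 4 on every crh-1 null array. The transthyretin-like gene ttr-14 went from 8.81 ± 0.4 to 2.67 ± 0.4 and dos-2, a gene of the Notch pathway, from 9.39 ± 0.1 to 3.3 ± 0.54. Where every array of one strain lay below a log2 value of 4, the fold is a lower bound, taken as the brighter mean against 4. On that basis ttr-14 was at least 28-fold, dos-2 at least 42-fold and the acyl-CoA dehydrogenase gene acdh-6 at least 21.3-fold lower. The collagen genes col-60 (-5.63 ± 0.35) and col-120 (-5.37 ± 0.4), dao-4 (-5.41 ± 0.23), srlf-19 (-4.54 ± 0.23) and the lipase gene lips-9 (-4.51 ± 0.2) fell as well. For these 8 genes adjusted p was 2.2e-08 to 1.32e-06. C38C6.3 (-5.41 ± 0.28), C14F11.4 (at least 16.6-fold lower) and C42D4.13 (at least 13.5-fold lower) led the falls among genes with sequence names only.

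The largest rise in these arrays was that of F26A1.8, from 3.1 ± 0 to 11.69 ± 0.1, at least 206-fold (adjusted p = 1.01e-09). Among genes with a class name, dbd-17 rose at least 23.1-fold, nspb-12 at least 7.46-fold and dct-5 at least 9.23-fold. The cation-transporting ATPase gene catp-3 (4.69 ± 0.55), dbd-20 (4.22 ± 0.32), idpp-12 (4.01 ± 0.36), abu-8 (3.99 ± 0.42) and the receptor tyrosine kinase gene kin-15 (3.96 ± 0.26) rose too. C34F11.8 (4.33 ± 0.26) and B0222.10 (3.99 ± 0.16) followed. In total 2132 of 10365 genes passed an adjusted p of 0.05, 1024 higher and 1108 lower, and 500 each way changed at least 2-fold. With arrays centred on their medians the balance turned, to 1104 higher and 995 lower. It was 1056 and 1037 with quantile normalization and 701 and 695 at an adjusted p of 0.01. The arrays of the pair of strains did not overlap for 43% of genes, against 10% by chance.

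Hedgehog-related genes, which encode secreted proteins of the cuticle-forming epidermis, fell as a group in crh-1 null. Of 33 measured, 17 fell, 6 rose and 10 did not pass (20 and 7 adjusted over the list alone, median log2 change -1.11, camera adjusted p = 6.98e-05, adjusted p = 0.123 with an estimated correlation). Examples were wrt-4 at -4.46 ± 0.19, grd-2 at -4.03 ± 0.18 and grl-5 at -3.53 ± 0.19. Among 33 moulting cycle genes, 18 fell, 6 rose and 9 did not pass (21 and 8 adjusted over the list alone, median log2 change -0.56, camera adjusted p = 0.00384, adjusted p = 0.426 with an estimated correlation). They included ptr-16 (-4.02 ± 0.27), ptr-18 (-2.85 ± 0.15) and mlt-10 (-2.56 ± 0.18) among the falls, while the fibrillin gene fbn-1 rose (2.52 ± 0.18). Cuticle collagens moved both ways. Of 125, 46 fell, 30 rose and 49 did not pass (49 and 32 adjusted over the list alone), and the list did not pass (median log2 change -0.19, camera adjusted p = 0.0566, adjusted p = 0.732 with an estimated correlation), although col-63 (-3.86 ± 0.13) and col-111 (-3.62 ± 0.16) fell steeply. Of 5 yolk protein genes, 4 fell, 0 rose and 1 did not pass (4 and 0 adjusted over the list alone, median log2 change -0.95, camera adjusted p = 0.00741, adjusted p = 0.57 with an estimated correlation). vit-4 was at least 7.98-fold lower, vit-1 changed by -0.95 ± 0.24 (lost without the filter on dim probe sets, adjusted p = 0.0579, and without crh-1 null replicate 2 or 3, adjusted p = 0.0507 and 0.0508), and vit-2 by -0.29 ± 0.24, which did not pass (adjusted p = 0.501).

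Of 30 oogenesis and eggshell genes in the same arrays, 12 fell, 0 rose and 18 did not pass (13 and 0 adjusted over the list alone, median log2 change -0.33, camera adjusted p = 0.000363, adjusted p = 0.57 with an estimated correlation), with the eggshell genes perm-4 at -2.17 ± 0.24, cpg-3 at -1.74 ± 0.26 and cbd-1 at -0.71 ± 0.12. Of 64 sperm genes, 3 fell, 1 rose and 60 did not pass (0 and 0 adjusted over the list alone, median log2 change -0.23, camera adjusted p = 0.00273, adjusted p = 0.59 with an estimated correlation). Of 44 germline proliferation and meiosis genes, 3 fell, 0 rose and 41 did not pass (2 and 0 adjusted over the list alone), rnr-1 among them (-1.2 ± 0.15), and the list was not called (camera adjusted p = 0.332).

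Of 19 epidermal antimicrobial peptide genes in crh-1 null, 9 rose, 2 fell and 8 did not pass (10 and 3 adjusted over the list alone, median log2 change 1.24, camera adjusted p = 0.00243, adjusted p = 0.57 with an estimated correlation). Rises included fipr-2 (2.34 ± 0.18), nlp-27 (2.24 ± 0.18) and cnc-8 (2.02 ± 0.16). Of 113 nuclear hormone receptor genes, 19 rose, 3 fell and 91 did not pass (19 and 3 adjusted over the list alone, median log2 change 0.28, camera adjusted p = 0.000189, adjusted p = 0.299 with an estimated correlation), among them nhr-23, a regulator of moulting (1.31 ± 0.13), and nhr-172 (2.64 ± 0.37). Of 21 pan-neuronal genes, 6 rose, 0 fell and 15 did not pass (8 and 0 adjusted over the list alone, median log2 change 0.25, camera adjusted p = 0.00449, adjusted p = 0.213 with an estimated correlation). Members included rab-3 at 0.66 ± 0.1 and ric-4 at 0.55 ± 0.11. Of 21 pharyngeal genes, 9 rose, 1 fell and 11 did not pass (12 and 3 adjusted over the list alone, median log2 change 0.49, camera adjusted p = 0.0118, adjusted p = 0.381 with an estimated correlation). Changes included marg-1 at 1.98 ± 0.25 and phat-3 at 0.77 ± 0.12. Calcium handling genes gave 6 rises and 1 fall among 36 (median log2 change 0.18, camera adjusted p = 0.00814, adjusted p = 0.299 with an estimated correlation), among them the calmodulin-like gene cal-5 (0.98 ± 0.13). In a list of 47 UDP-glucuronosyltransferases, 17 rose, 7 fell and 23 did not pass (19 and 9 adjusted over the list alone, median log2 change 0.18, camera adjusted p = 0.0451, adjusted p = 0.585 with an estimated correlation). That call was lost with quantile normalization (adjusted p = 0.056), median centring (adjusted p = 0.062) or the replicate block (adjusted p = 0.0522), and without any of 4 single arrays, WT replicates 2 and 3, crh-1 null replicate 3 or aak-2 o/e replicate 3 (adjusted p = 0.0517, 0.0672, 0.0547 and 0.0522). ugt-11 was at least 4.06-fold higher. In 32 dauer and steroid signalling genes, 6 rose, 1 fell and 25 did not pass (6 and 1 adjusted over the list alone, median log2 change 0.21, camera adjusted p = 0.0318, adjusted p = 0.57 with an estimated correlation). The call was lost without WT replicate 3 (adjusted p = 0.0544) or crh-1 null replicate 1 (adjusted p = 0.0574) and with probe sets averaged per gene (adjusted p = 0.0765), with daf-14 at 0.91 ± 0.12.

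Smaller shifts were called in crh-1 null for 22 lysozyme and saposin-like genes, of which 5 fell, 1 rose and 16 did not pass (5 and 1 adjusted over the list alone, median log2 change -0.23, camera adjusted p = 0.0248, adjusted p = 0.577 with an estimated correlation), spp-13 among them (-2.33 ± 0.21). Of 32 proteasome genes, 2 fell, 0 rose and 30 did not pass (0 and 0 adjusted over the list alone, median log2 change -0.19, camera adjusted p = 0.011, adjusted p = 0.57 with an estimated correlation), rpt-5 (-0.39 ± 0.1) and rpt-1 (-0.34 ± 0.11). The rpt-5 call ended without WT replicate 1 or crh-1 null replicate 2 (adjusted p = 0.0522 and 0.0614). That of rpt-1 ended with quantile normalization, median centring or the replicate block (adjusted p = 0.0502, 0.0571 and 0.0613) and without any single one of 9 arrays (adjusted p up to 0.124). Muscle markers gave no calls in 45 genes, intestinal markers 2 rises and 4 falls in 33, and epidermal markers 8 rises and 5 falls in 24. Of 22 genes of the AMPK, calcineurin and CREB pathway, 1 rose, the targeted gene crh-1 itself, and 1 fell. The ER chaperone genes hsp-3 (0.09 ± 0.13) and hsp-4 (0.5 ± 0.17), xbp-1 (0.37 ± 0.21) and sod-3 (-0.01 ± 0.15) did not pass, although hsp-4 did under 4 alternatives (adjusted p down to 0.00431, with array weights) and without 2 single arrays, tax-6 null replicate 1 (adjusted p = 0.0264) and aak-2 o/e replicate 1 (adjusted p = 0.0361). None of the 14 list calls in crh-1 null held with an estimated correlation.

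The arrays labelled tax-6 null differed most from WT. The adult cuticle collagen gene col-19 rose by 7.63 ± 0.33 on the log2 scale, a 198-fold change, and col-81 (8.55 ± 0.53), col-139 (6.49 ± 0.41) and col-129 (6.46 ± 0.5) rose with it. Genes near the lowest level in all WT arrays became bright: the F-box gene fbxa-163 rose at least 90-fold, the hedgehog-related genes grl-25 and grl-20 at least 30.6-fold and 27.8-fold, ZK813.1 at least 40.6-fold and ZK813.7 at least 25.7-fold. spig-20 (7.1 ± 0.37) and F08G2.5 (7.27 ± 0.34) rose as well. In the other direction, bcf-1 dropped from 13.99 ± 0.07 to 3.94 ± 1. The acyl-CoA dehydrogenase gene acdh-1, which acts in propionate and branched-chain amino acid breakdown, dropped from 12.7 ± 0.06 to 4.1 ± 0.18, a 389-fold change.

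Other steep falls in tax-6 null were those of acox-1.2, an acyl-CoA oxidase gene (-5.16 ± 0.21), pud-4 (-4.62 ± 0.23), pud-3 (-4.26 ± 0.29), the half-transporter gene haf-6 (-4.43 ± 0.29), the aspartyl protease gene asp-17 (at least 7.06-fold) and lips-14 (at least 5.53-fold). C50F7.9 (-3.72 ± 0.3), Y102A5C.6 (-3.54 ± 0.31) and Y46G5A.29 (-3.3 ± 0.12) led the sequence-named genes. For the 8 class-named rises adjusted p was 8.81e-13 to 1.21e-06. In all, 4664 genes passed, 1935 higher and 2729 lower, while 964 rose and 849 fell at least 2-fold. Arrays did not overlap for 54.5% of genes, against 10% by chance. Without replicate 1 of tax-6 null, the array that stood apart, 4810 genes passed, 4215 of them also called with all arrays. The other strains against WT moved more, since all arrays share 1 estimate of the spread. Without this array aak-2 o/e went from 3472 to 4391 genes and crh-1 null from 2132 to 2635.

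Neuropeptide genes rose almost throughout in tax-6 null. Of 47, 42 rose, 1 fell and 4 did not pass (43 and 1 adjusted over the list alone, median log2 change 1.34, camera adjusted p = 3.02e-17, adjusted p = 0.49 with an estimated correlation). Among these were flp-4 at 1.34 ± 0.12, flp-5 at 1.93 ± 0.18, nlp-18 at 1.38 ± 0.1 and nlp-35 at 1.7 ± 0.14. Of 18 insulin-like peptide genes, 11 rose, 1 fell and 6 did not pass (11 and 1 adjusted over the list alone, median log2 change 1.19, camera adjusted p = 6.98e-05, adjusted p = 0.57 with an estimated correlation). They included ins-35 (2.73 ± 0.18), ins-24 (2.87 ± 0.33) and ins-4 (1.93 ± 0.16). Of 21 pan-neuronal genes, 8 rose, 0 fell and 13 did not pass (7 and 0 adjusted over the list alone, median log2 change 0.2, camera adjusted p = 0.0147, adjusted p = 0.299 with an estimated correlation), among them the neuropeptide processing genes egl-3 (1.3 ± 0.16) and egl-21 (1.09 ± 0.13), the helper sbt-1 (1.22 ± 0.16) and ric-4 (0.39 ± 0.11). Neurotransmitter identity genes gave 1 rise and 1 fall in 11, and sensory neuron genes 3 rises and 2 falls in 9.

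Of 30 oogenesis and eggshell genes in tax-6 null, 22 rose, 0 fell and 8 did not pass (23 and 0 adjusted over the list alone, median log2 change 0.69, camera adjusted p = 1.5e-08, adjusted p = 0.381 with an estimated correlation). Genes included perm-4 at 2.6 ± 0.24, cpg-2 at 2 ± 0.17 and pos-1 at 1.64 ± 0.15. Of 125 collagens, 71 rose, 25 fell and 29 did not pass (71 and 27 adjusted over the list alone, median log2 change 0.62, camera adjusted p = 7.9e-08, adjusted p = 0.433 with an estimated correlation), col-158 and col-101 among the rises (at least 40.9-fold and 4.16 ± 0.17). Of 33 moulting cycle genes, 18 fell, 5 rose and 10 did not pass (20 and 5 adjusted over the list alone, median log2 change -0.6, camera adjusted p = 0.0196, adjusted p = 0.563 with an estimated correlation). The call was lost without tax-6 null replicate 2 (adjusted p = 0.0533), with nas-37 at -1.66 ± 0.16 and ptr-4 at -1.44 ± 0.12. Yolk protein genes did not move together: vit-2 rose (2.78 ± 0.24), vit-1 fell (-2.66 ± 0.24) and the other 3 did not pass (camera adjusted p = 0.772 for the list). Of 64 sperm genes, 25 fell, 3 rose and 36 did not pass (25 and 3 adjusted over the list alone), and the list was not called (camera adjusted p = 0.219). Of 24 histone genes, 13 fell, 1 rose and 10 did not pass (13 and 1 adjusted over the list alone, median log2 change -0.4, camera adjusted p = 0.0113, adjusted p = 0.57 with an estimated correlation). Examples were his-4 at -1.6 ± 0.15 and his-1 at -1.21 ± 0.15.

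Of 32 proteasome subunit genes in tax-6 null, 26 fell, 0 rose and 6 did not pass (30 and 0 adjusted over the list alone, median log2 change -0.51, camera adjusted p = 5.09e-06, adjusted p = 0.381 with an estimated correlation). They included rpt-6 (-0.61 ± 0.09), rpt-5 (-0.69 ± 0.1) and pas-1 (-0.51 ± 0.09). Of 29 ER folding and unfolded protein response genes, 17 fell, 1 rose and 11 did not pass (18 and 1 adjusted over the list alone, median log2 change -0.47, camera adjusted p = 0.00245, adjusted p = 0.381 with an estimated correlation), with the BiP genes hsp-3 at -1.14 ± 0.13 and hsp-4 at -0.72 ± 0.17, and the protein disulfide isomerase gene pdi-2 at -1.11 ± 0.1, while xbp-1 did not pass (-0.1 ± 0.21). Of 26 fatty acid beta-oxidation genes, 19 fell, 2 rose and 5 did not pass (19 and 3 adjusted over the list alone, median log2 change -0.63, camera adjusted p = 0.00243, adjusted p = 0.299 with an estimated correlation). The enoyl-CoA hydratase gene ech-6 fell (-1.42 ± 0.11), as did cpt-6 (-0.92 ± 0.13), while ech-9 rose (3.72 ± 0.33). Of 26 TCA and glyoxylate cycle genes, 12 fell, 0 rose and 14 did not pass (12 and 0 adjusted over the list alone, median log2 change -0.3, camera adjusted p = 0.00587, adjusted p = 0.57 with an estimated correlation). Members included mdh-2 at -0.8 ± 0.1 and sucg-1 at -1.18 ± 0.16. Of 36 oxidative phosphorylation genes, 12 fell, 0 rose and 24 did not pass (11 and 0 adjusted over the list alone, median log2 change -0.23, camera adjusted p = 0.0135, adjusted p = 0.253 with an estimated correlation). The call was lost with quantile normalization (adjusted p = 0.0949).

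Of 18 genes of the intracellular pathogen and pmk-1 responses in tax-6 null, 10 rose, 1 fell and 7 did not pass (10 and 1 adjusted over the list alone, median log2 change 0.6, camera adjusted p = 0.00151, adjusted p = 0.182 with an estimated correlation). Rises included irg-1 (4.7 ± 0.23), irg-4 (2.06 ± 0.15) and skr-3 (1.5 ± 0.1). Of 19 epidermal antimicrobial peptide genes, 7 rose, 2 fell and 10 did not pass (8 and 2 adjusted over the list alone, median log2 change 0.38, camera adjusted p = 0.00621, adjusted p = 0.585 with an estimated correlation). Changes included fipr-24 at 4.26 ± 0.25. Of 113 F-box and BTB-MATH genes, 37 rose, 14 fell and 62 did not pass (37 and 14 adjusted over the list alone, median log2 change 0.07, camera adjusted p = 0.00223, adjusted p = 0.381 with an estimated correlation). The call was lost without the filter on dim probe sets (adjusted p = 0.0612), with fbxa-60 at 2.32 ± 0.12. Of 46 abu and pqn genes, 20 rose, 5 fell and 21 did not pass (20 and 5 adjusted over the list alone, median log2 change 0.05, camera adjusted p = 0.00325, adjusted p = 0.585 with an estimated correlation), abu-15 among them (4.93 ± 0.36). Of 113 nuclear hormone receptor genes, 37 rose, 9 fell and 67 did not pass (36 and 8 adjusted over the list alone, median log2 change 0.24, camera adjusted p = 0.00245, adjusted p = 0.381 with an estimated correlation), and of 32 dauer and steroid signalling genes, 14 rose, 1 fell and 17 did not pass (14 and 1 adjusted over the list alone, median log2 change 0.38, camera adjusted p = 0.00188, adjusted p = 0.401 with an estimated correlation). The superoxide dismutase gene sod-3 rose (1.9 ± 0.15). Of 31 glutathione S-transferase and glutathione synthesis genes, 9 rose, 10 fell and 12 did not pass (10 and 10 adjusted over the list alone), and the list was not called (camera adjusted p = 0.273).

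Among tissue markers, muscle genes gave 13 falls and 0 rises in 45 (median log2 change -0.25, camera adjusted p = 0.0248, adjusted p = 0.586 with an estimated correlation). The call was lost without tax-6 null replicate 1 (median -0.12, adjusted p = 0.126) or WT replicate 1 (adjusted p = 0.0525) and with quantile normalization (adjusted p = 0.0823), array weights (adjusted p = 0.0755) or the stricter filter (adjusted p = 0.0551). zig-12 (-0.81 ± 0.11) and unc-95 (-0.7 ± 0.09) were among them. Intestinal markers gave 9 rises and 13 falls in 33, pharyngeal markers 4 and 1 in 21, epidermal markers 8 and 9 in 24 and germline genes 1 and 8 in 44, and none of these lists was called. Hedgehog-related genes split into 12 rises and 15 falls in 33, with a median of -0.3 but a mean of 0.53. None of the 19 list calls in tax-6 null held with an estimated correlation.

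In the arrays labelled aak-2 o/e, the yolk protein gene vit-5 and the collagen genes col-81 and col-19 were among the largest rises, and plk-3 fell furthest. There vit-5 went from 5.4 ± 0.65 to 10.29 ± 0.4, vit-4 from 7 ± 0.63 to 11.26 ± 0.42 and vit-2 from 7.04 ± 0.08 to 10.71 ± 0.34, and all 5 yolk protein genes measured rose (5 adjusted over the list alone; median log2 change 3.67, camera adjusted p = 7.25e-06, adjusted p = 0.381 with an estimated correlation). The collagen genes col-81 (5.57 ± 0.53), col-19 (5.37 ± 0.33), col-129 (4.57 ± 0.5) and col-139 (4.04 ± 0.41) and the phospholipid scramblase gene scrm-4 (4.53 ± 0.15) rose too. F26A1.8 rose at least 19.1-fold, F54F7.3 at least 13.5-fold and C30H6.5 at least 10.5-fold. The Polo-like kinase gene plk-3 fell from 10.13 ± 0.11 to 3.38 ± 0.25, at least 70-fold (adjusted p = 4.13e-09).

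The next falls in aak-2 o/e were those of fbxa-193 (at least 4.58-fold), the acyl-CoA synthetase gene acs-2 (-3.53 ± 0.53), bath-5 (-3.06 ± 0.18), bath-7 (at least 3.04-fold), fbxa-107 (-3.02 ± 0.2), slc-25A18.2 (-2.86 ± 0.25) and scl-10 (at least 3.35-fold). C16C8.4 (-3.88 ± 0.17), C16C8.5 (-3.51 ± 0.23) and F55G1.6 (-3.43 ± 0.11) followed among sequence-named genes. For the 8 class-named falls adjusted p was 4.13e-09 to 0.00032. In total 3472 genes passed, 1467 higher and 2005 lower, but 1020 rose and 300 fell at least 2-fold. The median log2 change over all genes was -0.15, so many small falls lay close to that median. At an adjusted p of 0.01 the balance turned, to 1212 higher and 979 lower. Arrays did not overlap for 52.5% of genes, against 10% by chance.

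Sperm genes rose as a block in aak-2 o/e. Of 64, 56 rose, 0 fell and 8 did not pass (57 and 0 adjusted over the list alone, median log2 change 1, camera adjusted p = 2.29e-28, adjusted p = 0.182 with an estimated correlation). Among these were ssp-16 at 2.57 ± 0.12, ssp-34 at 2.32 ± 0.18 and the sperm phosphatase gene gsp-3 at 1.71 ± 0.14. Of 30 oogenesis and eggshell genes, 21 rose, 0 fell and 9 did not pass (23 and 0 adjusted over the list alone, median log2 change 0.65, camera adjusted p = 4.55e-10, adjusted p = 0.381 with an estimated correlation). Genes included perm-4 at 2.31 ± 0.24, perm-2 at 2.07 ± 0.2 and egg-1 at 1.5 ± 0.19. Of 125 collagens, 49 rose, 13 fell and 63 did not pass (54 and 16 adjusted over the list alone, median log2 change 0.34, camera adjusted p = 3.17e-09, adjusted p = 0.381 with an estimated correlation), among them col-159 (1.92 ± 0.17) and col-12 (1.36 ± 0.12). Of 46 abu and pqn genes, 13 rose, 3 fell and 30 did not pass (13 and 4 adjusted over the list alone, median log2 change 0.12, camera adjusted p = 0.00909, adjusted p = 0.59 with an estimated correlation), abu-15 rising by 2.93 ± 0.36. Of 33 moulting cycle genes, 16 fell, 3 rose and 14 did not pass (16 and 3 adjusted over the list alone, median log2 change -0.4, camera adjusted p = 0.0492, adjusted p = 0.57 with an estimated correlation). Examples were noah-2 at -0.99 ± 0.11 and nas-37 at -1.38 ± 0.16. That call was lost with quantile normalization or the stricter filter (adjusted p = 0.0551 each), with the replicate block (adjusted p = 0.0616) and without any of 8 single arrays (adjusted p up to 0.0872, without aak-2 o/e replicate 3). Of 44 germline proliferation and meiosis genes, 6 rose, 4 fell and 34 did not pass (6 and 4 adjusted over the list alone), and the list was not called (camera adjusted p = 0.564).

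Of 47 neuropeptide genes in aak-2 o/e, 9 fell, 0 rose and 38 did not pass (7 and 0 adjusted over the list alone, median log2 change -0.32, camera adjusted p = 0.0116, adjusted p = 0.777 with an estimated correlation). Members included nlp-15 at -1 ± 0.15 and nlp-16 at -0.63 ± 0.13. Of 113 nuclear hormone receptor genes, 32 fell, 1 rose and 80 did not pass (30 and 1 adjusted over the list alone, median log2 change -0.3, camera adjusted p = 0.0166, adjusted p = 0.49 with an estimated correlation). The call was lost without the filter on dim probe sets (adjusted p = 0.134), with nhr-137 at -2.1 ± 0.23 and nhr-21 at -1.62 ± 0.21. F-box and BTB-MATH genes gave 27 falls and 9 rises in 113 without a list call (camera adjusted p = 0.273). Muscle markers gave 3 falls in 45, intestinal markers 7 in 33, pharyngeal markers 5 in 21 and pan-neuronal genes 5 in 21, with no rise in any of these lists, and epidermal markers 11 falls and 3 rises in 24, and none was called. Of 22 AMPK, calcineurin and CREB pathway genes, 4 fell, aakb-2 among them (-0.49 ± 0.14, lost without WT replicate 1 or 2 or aak-2 o/e replicate 2, adjusted p = 0.0758, 0.08 and 0.0738). hsp-4 rose (0.94 ± 0.17), sod-3 fell (-0.56 ± 0.15, lost without WT replicate 1, adjusted p = 0.054), and hsp-3 (-0.23 ± 0.13) and xbp-1 (0.24 ± 0.21) did not pass. None of the 8 list calls in aak-2 o/e held with an estimated correlation.

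**Figure D1:**
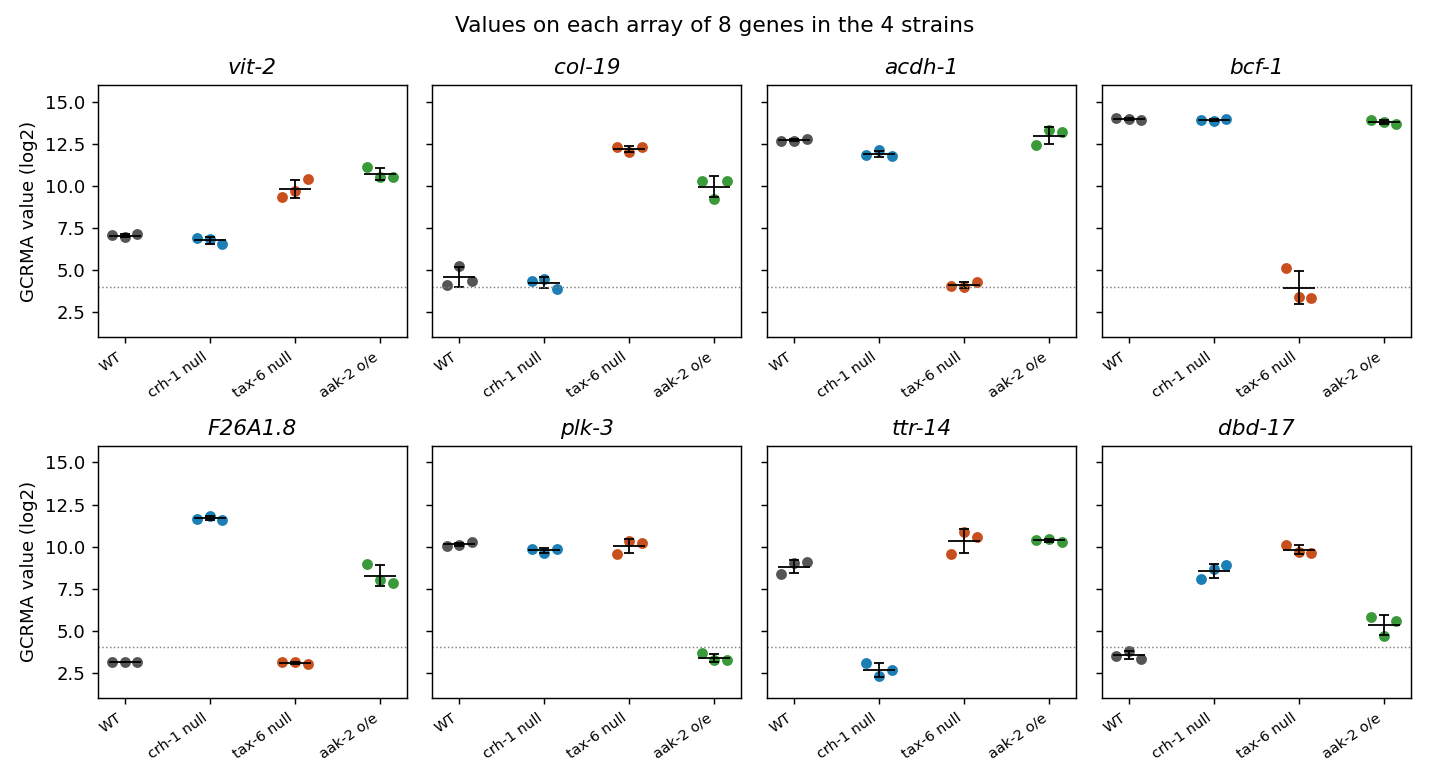
GCRMA values on the log2 scale (vertical axis) of 8 genes on each of the 12 arrays, by strain (horizontal axis); points are arrays, bars the mean ± SD of 3 arrays, and the dotted line a log2 value of 4. bcf-1 and acdh-1 drop in tax-6 null, plk-3 in aak-2 o/e and ttr-14 in crh-1 null, while col-19 rises in tax-6 null and aak-2 o/e.

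**Figure D2:**
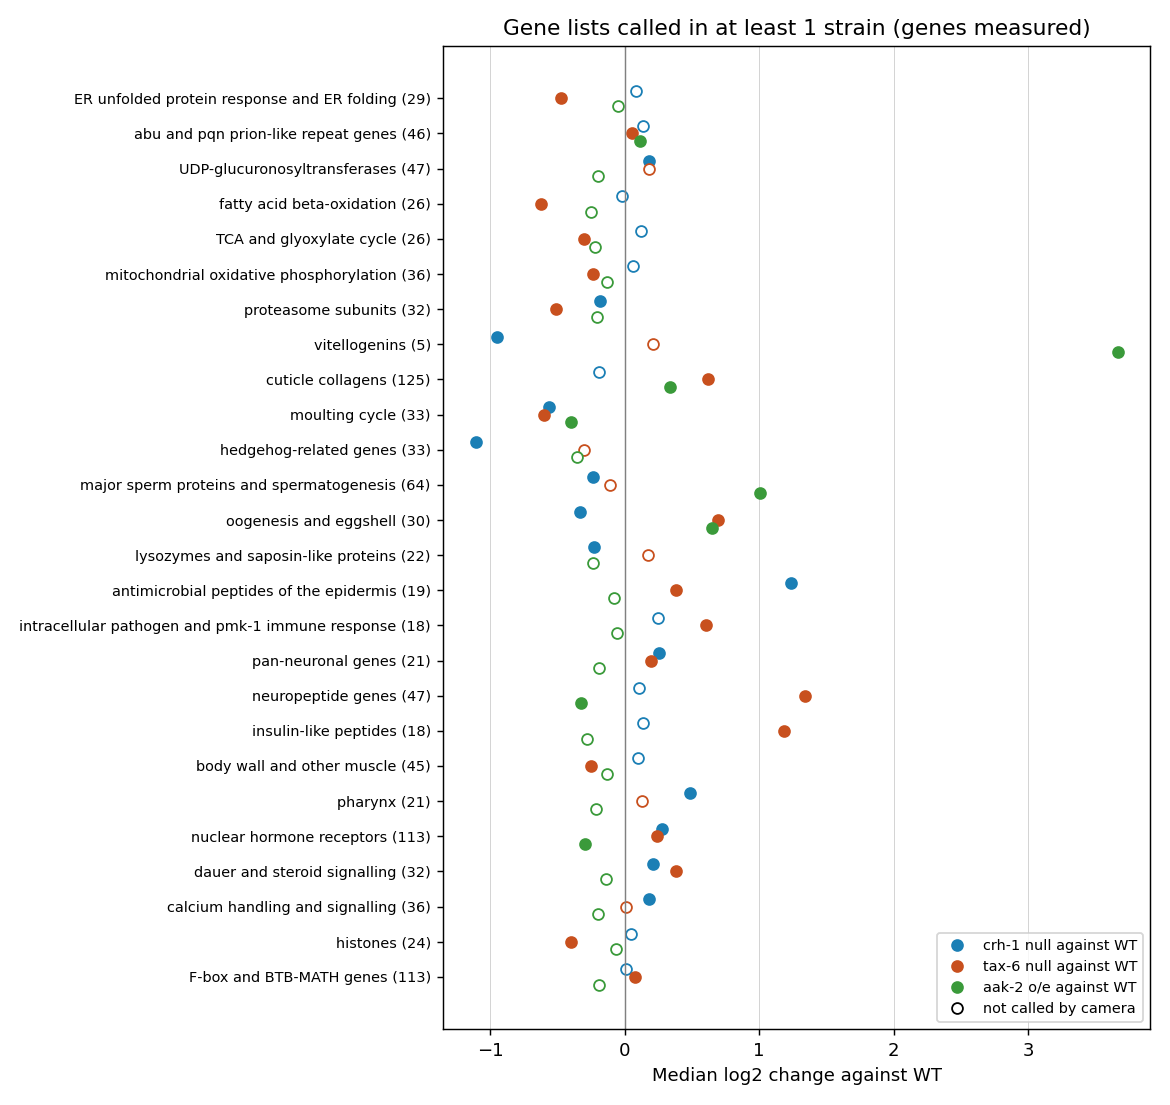
Median log2 change against WT (horizontal axis) of each gene list called in at least 1 strain, with the number of genes measured; colours are strains, and filled points were called by camera at the preset correlation of 0.01. Yolk protein genes lie at -0.95 in crh-1 null and 3.67 in aak-2 o/e, and neuropeptide genes at 1.34 in tax-6 null and -0.32 in aak-2 o/e.

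Genes shared by the 3 strains were counted because the series title places their genes in 1 pathway. Called against WT in the same direction in all 3 strains were 92 higher and 285 lower genes. Rises included dbd-20 (4.22 in crh-1 null, 5.82 in tax-6 null and 3.32 in aak-2 o/e), abu-8 (3.99, 5.06 and 2.99 in the same order), idpp-12, dbd-13, dct-5, pqn-54, abu-15 and C23G10.11. Falls included scl-10 (at least 3.35-fold in each strain), gly-1 (-3.15, -3.07 and -2.1), T05A8.6, C50F7.9, C26B9.2, npax-2, gtnt-18 and npr-41. Independent lists of these sizes would share 27.1 and 56.4 genes, and unchanged groups simulated against shared simulated WT arrays had 0 in common. No gene was changed in that simulation, so few calls could arise. It therefore cannot show how far shared WT arrays add to overlap among changed genes. The 3 WT arrays enter every comparison and are too few to divide between them, so part of the excess may come from the shared controls. When another strain served as the reference, a comparison added after the data were seen, 824 genes were shared with crh-1 null, 1980 with tax-6 null and 1970 with aak-2 o/e as reference, all more than with WT. Together the shared rises and falls against WT numbered 208 at an adjusted p of 0.01 and 573 with array weights.

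crh-1 null and tax-6 null shared most with each other: 616 genes rose and 752 fell in both, against 191.2 and 291.7 for independent lists, and of 1543 genes called in both 88.7% moved the same way. The balance of 616 and 752 turned to 670 and 658 with arrays centred on their medians and to 301 and 228 with a 2-fold minimum. Shared rises included dbd-17 (at least 23.1-fold in crh-1 null and 56.1-fold in tax-6 null), nspb-12 and C34F11.8. Shared falls included pud-4 (-4.02 in crh-1 null and -4.62 in tax-6 null) and dos-2 (at least 42-fold and -3.46). The log2 changes correlated across genes at r = 0.462, with 0.5 in simulations without effects. Their covariance was 0.341 against a simulated 0.017. crh-1 null and aak-2 o/e shared 108 rises and 339 falls against 144.9 and 214.3 for independent lists, and 44.5% of 1005 genes called in both moved the same way (r = -0.0339, covariance -0.0188 against a simulated 0.017). F26A1.8 and catp-3 (4.69 and 3.48) were among the shared rises. tax-6 null and aak-2 o/e shared 297 rises and 788 falls against 273.9 and 527.9, and 52.4% of 2072 genes called in both moved the same way (r = 0.1, covariance 0.0712 against a simulated 0.0171). With a 2-fold minimum the balance turned, as 173 of 292 shared genes rose. The collagen genes col-19, col-81 and col-129 and F54F7.3 led the shared rises, and acs-2 the shared falls (-3.26 and -3.53). Genes are not independent replicates.

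**Figure D3:**
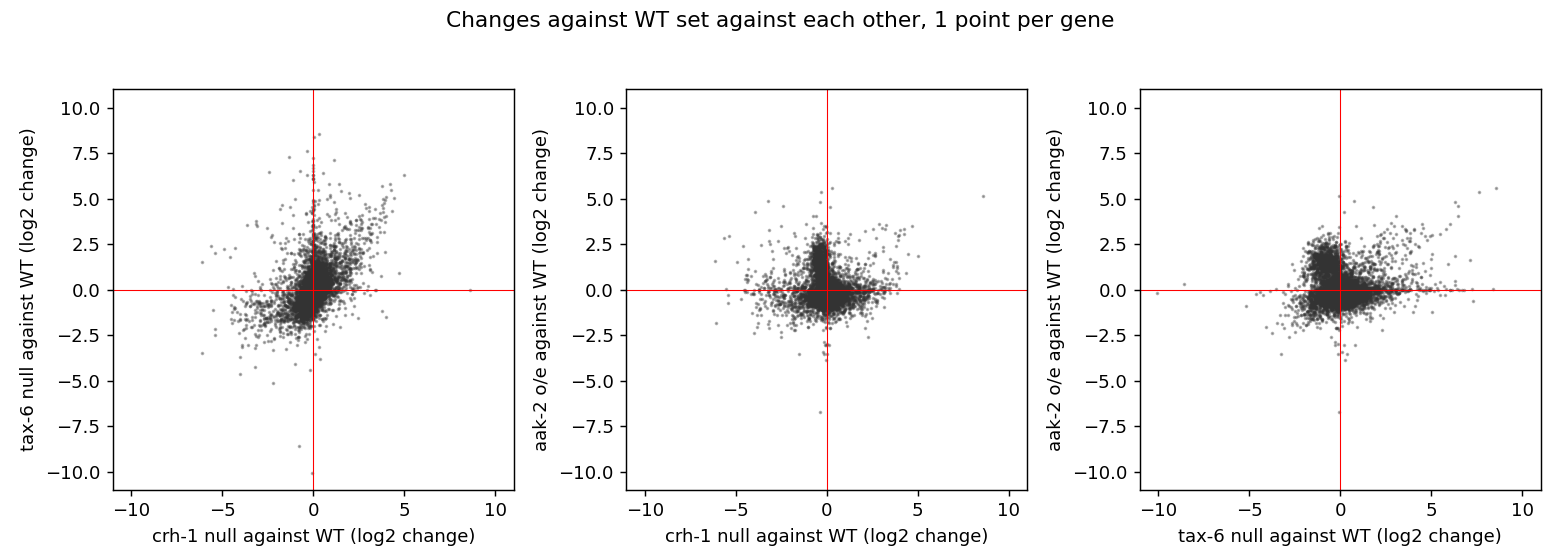
Log2 change against WT of 10365 genes in one altered strain (horizontal axis) and another (vertical axis), 1 point per gene, for the 3 pairs of strains; red lines mark 0. Pearson r was 0.462 (crh-1 null and tax-6 null), -0.0339 (crh-1 null and aak-2 o/e) and 0.1 (tax-6 null and aak-2 o/e). It was 0.5 in simulations of unchanged strains that share simulated WT arrays.

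Direct contrasts tested where the altered strains differed. Between tax-6 null and aak-2 o/e, 5188 genes differed, 2865 higher and 2323 lower in tax-6 null, while 1218 were higher and 1261 lower at least 2-fold. Higher in tax-6 null were fbxa-163 (at least 90-fold), grl-25 (at least 30.6-fold), grl-20 (at least 27.8-fold) and plk-3 (at least 65.7-fold), and bcf-1 (-9.84 ± 0.35), acdh-1 (-8.89 ± 0.2), pud-4 (-4.38 ± 0.23) and haf-6 (-4.31 ± 0.29) were lower. Of 47 neuropeptide genes, 46 were higher and 1 lower in tax-6 null (median log2 change 1.67, camera adjusted p = 9.26e-15, adjusted p = 0.353 with an estimated correlation), and of 64 sperm genes 60 were lower and 1 higher (median log2 change -1.45, camera adjusted p = 6e-18, adjusted p = 0.156 with an estimated correlation).

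Between crh-1 null and tax-6 null, 3933 genes differed, 2213 higher and 1720 lower in crh-1 null, but at least 2-fold 476 were higher and 859 lower. In crh-1 null, bcf-1 (10 ± 0.35), acdh-1 (7.81 ± 0.2), nspe-7 (4.95 ± 0.35) and haf-6 (4.26 ± 0.29) were higher, and col-129 (-8.88 ± 0.5), fbxa-163 (at least 90-fold), col-81 (-8.24 ± 0.53) and col-60 (-8.01 ± 0.35) lower. Hedgehog-related genes were lower in crh-1 null (20 of 33 lower and 3 higher; median log2 change -0.9, camera adjusted p = 3.71e-07, adjusted p = 0.0336 with an estimated correlation), the single list call that held with an estimated correlation among all 6 comparisons. Between crh-1 null and aak-2 o/e, 4807 genes differed, 2837 higher and 1970 lower in crh-1 null, but at least 2-fold 920 were higher and 1411 lower. Here plk-3 (at least 54.3-fold), dct-7 (4.06 ± 0.63), ptr-8 (4.06 ± 0.31) and kin-15 (3.92 ± 0.26) were higher in crh-1 null, and col-60 (-8.45 ± 0.35), col-120 (-8.34 ± 0.4), vit-4 (at least 153-fold) and vit-5 (at least 78.4-fold) lower. All 5 yolk protein genes were lower in crh-1 null than in aak-2 o/e (median log2 change -3.96, camera adjusted p = 2.92e-05, adjusted p = 0.277 with an estimated correlation).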

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

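The tests of shared probe sets were chosen only after the results were seen, while the predictions on developmental stage and on other groupings of the arrays were written first. Genes that moved in opposite directions against WT in 2 strains, and differed between those strains directly, drew attention as differences between groups. There were 175 such genes between crh-1 null and tax-6 null, 558 between crh-1 null and aak-2 o/e and 987 between tax-6 null and aak-2 o/e. Gene lists with opposite directions did so too, each with a called direct contrast. Yolk protein genes were lower in crh-1 null than in aak-2 o/e (median log2 change -3.96, adjusted p = 0.277 with an estimated correlation), as were sperm genes (-1.23, adjusted p = 0.156 with an estimated correlation). Oogenesis and eggshell genes were lower in crh-1 null than in tax-6 null (-0.94) and aak-2 o/e (-0.93), with adjusted p = 0.161 and adjusted p = 0.235 with an estimated correlation. Nuclear hormone receptor genes were higher in crh-1 null (0.61) and in tax-6 null (0.596) than in aak-2 o/e (adjusted p = 0.156 for each with an estimated correlation), and neuropeptide genes were higher in tax-6 null than in aak-2 o/e (1.67, adjusted p = 0.353 with an estimated correlation). Groups of 3 arrays are too small for a test of a single array far from the others.

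Yolk protein and adult collagen genes may differ because pools were frozen at different points of late larval growth. On that reading oogenesis and eggshell genes should be lower in the younger pools and higher in the older ones. Their median log2 changes were -0.33 in crh-1 null, 0.69 in tax-6 null and 0.65 in aak-2 o/e. These signs match an earlier stage in the first and a later stage in the others. None of these list calls by camera held with an estimated correlation (adjusted p = 0.57, 0.381 and 0.381). Sperm genes split the strains read as later. In aak-2 o/e 56 of 64 rose and 0 fell, while 25 fell and 3 rose in tax-6 null. No direction was predicted for sperm genes, and these strains may differ in how late they were frozen. The split therefore does not argue against stage. Of 1543 genes called in both crh-1 null and tax-6 null, read as opposite in stage, 88.7% moved the same way. Both comparisons use the same WT arrays, which may add to this share. A gene at its highest near the WT stage would also be lower in younger and older pools alike. Moulting cycle genes fell more often than they rose in all 3 altered strains. The shared direction therefore does not argue against stage. The yolk protein list was not called in tax-6 null, where vit-2 rose and vit-1 fell. How much of the pattern stage covers therefore stays open. Binding of probe sets to several collagens did not account for the rises, since among 68 collagens without a shared-sequence suffix 37 rose and 13 fell in tax-6 null, and 23 rose and 8 fell in aak-2 o/e. The strain itself remains a biological explanation that these data cannot separate from stage, because harvest times are not given in the sources used here.

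Other groupings of the arrays were counted. In each of the 6 comparisons only 1 of 10 splits of the 6 arrays, the real one, called as many genes (2132, 4664 and 3472 for crh-1 null, tax-6 null and aak-2 o/e against WT, 5188 for tax-6 null against aak-2 o/e, 3933 for crh-1 null against tax-6 null and 4807 for crh-1 null against aak-2 o/e). The highest other split called 0, or 1 for crh-1 null against tax-6 null, and 10 splits are too few for a share under 0.05. Every other split also mixes arrays of both strains, so the strain difference enters the spread and few calls can arise. The low counts are therefore no evidence for the real grouping. For the genes shared by all 3 strains (92 higher and 285 lower), 3 of 100 regroupings of the 12 arrays shared as many, the real one included, with 948 as the highest other, so mixed strains can share more than the real ones.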

How the results depend on the processing

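Apart from stricter thresholds and array weights, every count of changed or shared genes stayed within 1.5 times its value under each alternative. No named gene, called list or targeted probe set changed direction with a call under any alternative. Called genes that were not named were not checked for direction. The balance of higher and lower counts turned in 5 of 6 comparisons with a 2-fold minimum. It also turned in crh-1 null under both normalizations, and in crh-1 null and aak-2 o/e at an adjusted p of 0.01. At an adjusted p of 0.01, crh-1 null gave 1396 genes and aak-2 o/e 2191, and shared genes fell to 208 in all 3 strains, 829 in crh-1 null and tax-6 null, 237 in crh-1 null and aak-2 o/e and 574 in tax-6 null and aak-2 o/e. With a 2-fold minimum the counts were 1000, 1813 and 1320 for crh-1 null, tax-6 null and aak-2 o/e. They were 2479, 1335 and 2331 for the direct contrasts tax-6 null against aak-2 o/e, crh-1 null against tax-6 null and crh-1 null against aak-2 o/e. Shared genes then numbered 121, 529, 139 and 292. Array weights, whose estimation gave convergence warnings, raised genes shared by all strains to 573 and by crh-1 null and aak-2 o/e to 703. Leaving out only tax-6 null replicate 1, the array that stood apart, raised these counts to 526 and 633. Those were the highest values with any single array left out, so this array may account for much of the rise. Array weights also took 1 aak-2 probe set past the threshold (-0.506). The tax-6 probe set, near background, lost its call with median centring (-0.426), and at -0.471 with only the 2 strains compared. Leaving out each array gave -0.6 to -0.305 and -0.536 to -0.386 for the aak-2 probe sets and -0.564 to -0.314 for tax-6; fewer arrays were tested. With an estimated correlation 0 of 41 lists were called. Of 584 named changes called, 511 kept their call under all alternatives but the thresholds, wherever the gene was tested. Genes that the stricter filter removed were not tested under it. They count as kept if no other alternative ended their call. As 29.8% of values lay within 0.1 of the lowest value, changes among dim genes could be missed.

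As a replicate block, the replicate number left 1926, 4399 and 3181 genes against WT and ended the tax-6 call (-0.471). Deviations of same-numbered arrays correlated at -0.249 to 0.138 (median -0.0904), above 0.1 in 1 of 18 pairs. Those of differently numbered arrays correlated at -0.253 to 0.281 (median 0.0236), above 0.1 in 13 of 36 pairs. Between WT and crh-1 null all same-numbered values were positive (0.0788, 0.138 and 0.0475), while every other pair of strains held a negative one. Deviations from the mean of so few arrays are tied to each other. These correlations therefore cannot decide whether the numbers pair samples.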

Other observations

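The methionine cycle, propionate and neighbourhood tests in this part were chosen only after the results were seen. In tax-6 null the fall of acdh-1 extended to other genes of the propionate shunt, a route that breaks down propionate without vitamin B12. hphd-1 (-2.85 ± 0.11), hach-1 (-1.63 ± 0.1) and ech-6 (-1.42 ± 0.11) fell, while alh-8 did not pass (-0.1 ± 0.12). The transcription factor gene nhr-68 (-2.62 ± 0.17) and nhr-114 (-1.13 ± 0.37) were lower as well. The fall of nhr-68 was also called in crh-1 null (-0.83 ± 0.17, adjusted p = 0.00359) and in aak-2 o/e (-0.54 ± 0.17, adjusted p = 0.0276). nhr-114 passed in neither. nhr-10, the other regulator examined, did not pass in tax-6 null (0.29 ± 0.18, adjusted p = 0.209) and rose in crh-1 null (0.61 ± 0.18, adjusted p = 0.0282). None of the 4 genes of the B12-dependent route (pcca-1, pccb-1, mmcm-1 and mce-1) passed in tax-6 null or crh-1 null. In aak-2 o/e mce-1 was lower (-0.61 ± 0.15, adjusted p = 0.00869) and the others did not pass. In crh-1 null 3 of 5 shunt genes fell (median log2 change -0.36), and in aak-2 o/e 0 of 5 changed.

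The shunt genes fell further than 58 TCA cycle and oxidative phosphorylation genes, with a median of -1.63 against -0.255. The lowest of those was -1.18, so 0% lay at or below the shunt median. The shunt set was chosen after the fall of acdh-1 was seen. The fatty acid beta-oxidation list, which holds acdh-1 and ech-6, fell too (19 of 26 lower and 2 higher, median -0.63). This comparison therefore cannot exclude a wider fall of mitochondrial enzymes. Repression by ample vitamin B12 predicted lower methionine and S-adenosylmethionine cycle genes. Their median was -0.58 with 6 of 11 lower and 1 higher in tax-6 null, among them mel-32 (-0.89 ± 0.12), pmt-2 (-0.78 ± 0.1), sams-1 (-0.71 ± 0.1) and mtrr-1 (-1.15 ± 0.12), which is consistent with it, although the set and its limits were chosen after its values were seen. The same set had a median of -0.38 with 5 of 11 lower in aak-2 o/e, where no shunt gene changed, so the set does not single out this cause. Vitamin B12 was not measured.

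In aak-2 o/e, 27 of 113 F-box and BTB-MATH genes were lower, although the list was not called (camera adjusted p = 0.273). Of the 27, 14 had a directly adjacent tested gene that was also lower, against 9.79 on average in 100000 random draws from the list (permutation p = 0.046). This may reflect change shared along chromosome neighbourhoods, but the value lay barely under 0.05 and the test followed a look at neighbouring genes. A shared-sequence suffix was not more frequent among the lower genes, at 11% against 23.3% of the others (Fisher exact p = 0.272). That comparison did not test whether probe sets of adjacent genes bind the same transcripts.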
